A study of Rattus norvegicus with 72 samples.

How the data were processed

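The series measured microRNAs (miRNAs) bound to Argonaute 2 (Ago2), the protein that carries mature miRNAs to their target transcripts, in 3 hippocampal subfields of Sprague-Dawley rats: CA1, CA3 and the dentate gyrus (DG). The animals underwent perforant pathway stimulation, a stimulation of the main cortical input to the hippocampus that is followed by epilepsy. Each subfield has a control group and 7 periods after stimulation (1 hour, 24 hours, 72 hours, 10 days, 16 days, the day of the first seizure, and the chronic period), with 3 libraries in each group and 72 libraries in all. The labels do not say how the control group was treated. Libraries are named here by the number in their titles. The labels do not state that the libraries of a group came from separate animals, so p-values measure the spread between these samples.

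Per the labels' protocols, frozen hippocampal tissue was homogenised, Ago2 was pulled down with an antibody, and libraries were made with the TruSeq small RNA kit. The deposited values are whole-number read counts per miRNA, in 1 table per subfield, not normalised. Cutadapt 1.2.1 and Bowtie 0.12.8 are named in the submitters' processing notes. The genome build, the miRNA annotation and the handling of reads that match several miRNAs are not given in the sources used here. Levels of near-identical family members (let-7, miR-181, miR-376, miR-200) are therefore uncertain to that extent, and no coordinates are given. A pull-down reads the loaded pool of each library, so every value is relative to the other miRNAs of that library. The tables list 536 miRNAs in CA1, 543 in CA3 and 546 in the DG, of which 520 are in all tables and 565 in any.

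From these counts, each subfield was fitted on its own with edgeR 4.0.16 in R 4.3.3, over its 8 groups together: TMM normalisation, the default expression filter by group (minimum count 10), and the quasi-likelihood F test. The filter left 422, 436 and 436 miRNAs in CA1, CA3 and the DG, which held 99.99% of the counts in each. Each period was tested against control, and 1 further test asked whether any period differed. A miRNA was called at an adjusted p under 0.05 (Benjamini-Hochberg over the miRNAs tested). Fold changes are on the log2 scale with the standard error (SE) taken as the fold change divided by the square root of F, and levels are TMM-scaled CPM (counts scaled to the size of the library) with the SD over libraries. Control libraries of different subfields were compared, and subfield differences in the response tested by interaction terms, in 1 fit of all 72 libraries over the 451 miRNAs that passed the filter among those in all tables. All periods of a subfield share its 3 control libraries, so a control library that stands apart enters every comparison. The comparison of the chronic period with the first seizure was added after the data were seen.

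The 54 libraries of the control group and the first 5 periods held 1891656 to 4120659 counts, and the 18 of the first seizure and chronic period 5154825 to 13411245. A floor of 3 counts corresponds to 0.728 to 1.59 CPM in the shallower and 0.224 to 0.582 CPM in the deeper libraries, for counting error only. No pair of libraries within a group was a duplicate: over 72 pairs, the lowest chi-square per degree of freedom was 75.7 and 0 pairs were identical.

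Before the data were examined, 16 lists of miRNAs were fixed from general knowledge: clusters (miR-132/miR-212, miR-379-410 and miR-127/miR-136 of the imprinted Dlk1-Dio3 region, miR-17-92, miR-183/miR-96/miR-182), families (let-7, miR-181), cell markers (microglia and leukocytes, oligodendrocytes, neurons, vessels, red blood cells, choroid plexus with ciliated epithelium, and miR-23/26/29, which are higher in cultured astrocytes), inflammation-associated miRNAs and seizure-associated miRNAs. Of the members that are in the tables, 15 of the seizure-associated list, 5 of the inflammation list, 4 of the neuron list, 3 of the microglia list, 2 of the miR-132/miR-212 list and 1 each of the miR-379-410, miR-127/miR-136, oligodendrocyte and miR-23/26/29 lists stand in another list; the others share 0. The seizure-associated list rests on knowledge of the field that may include these samples, so its counts are not independent evidence of a direction. Lists with at least 3 tested members were compared with all other miRNAs by camera (limma 3.58.1, preset correlation 0.01, prior count 2), adjusted over all lists and periods of a subfield. The miR-183/miR-96/miR-182 list had 2 tested members and got no test. Each call was repeated with an estimated correlation, and with fry, which tests whether a list's members move one way and does not compare them with other miRNAs. Counts of members "adjusted over the list alone" use the list's own p-values.

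The miRNAs named come from a set given by a rule fixed at the same time. It takes, per subfield and period, up to 3 miRNAs with the largest rise and 3 with the largest fall among those called, with a mean of at least 10 CPM in 1 group and all 3 libraries on the same side of all 3 controls. It also takes miR-132-3p, miR-212-3p, miR-134-5p, miR-146a-5p, miR-21-5p, miR-10a-5p, miR-142-5p, miR-124-3p, miR-128-3p, miR-129-5p, miR-219a-5p and miR-211-5p whatever their result. Further, it takes up to 4 members of each list with the smallest p in the test of any period, up to 8 called miRNAs per direction between subfields in controls, and the 10 with the smallest p for a subfield difference in any period.

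Alternatives were RLE size factors, total counts without a TMM factor, no filter, DESeq2 1.42.0, a fit of only the groups compared, leaving out each library in turn, and the title number as a replicate block where subfields are compared. In the controls all pairs of libraries of 1 title number deviated together from their group means (correlations of 0.184 to 0.420 between CA3 and CA1, 0.357 to 0.496 between the DG and CA1 and 0.223 to 0.450 between the DG and CA3), so that the numbers were taken to pair the control libraries from the data, after the counts of calls had been seen. Over all groups the rule set for pairing was not met, so subfield differences in the response were fitted without a block. There 19, 21 and 21 of 24 libraries still correlated best with their own number among the 3 of their period (CA3 and CA1, DG and CA1, DG and CA3). The lowest correlation of each pair of subfields lay in the chronic period, where 1 of 3 libraries did so. Libraries of 1 number can thus not be taken as independent, and blocked counts are given as an alternative. Added after the data were seen were a choroid plexus marker covariate, a fit without 8 libraries high in the choroid plexus miRNA miR-204-5p, and thinning all libraries to 1 depth. The procedure was tested on simulated data with 200 changed miRNAs, as many raised as lowered, and with libraries drawn independently. The shares recovered may thus be higher than in comparisons where few miRNAs change or single libraries stand apart. At 16 days in the DG, 95.5% of 4-fold, 61.2% of 2-fold and 29.9% of 1.5-fold changes were recovered among 436 miRNAs; in CA1 these shares were 86.4%, 37.3% and 13.4% among 422, and in CA3 86.4%, 37.3% and 14.9% among 436. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.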

Results

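Ago2-bound miRNAs were counted in CA1, CA3 and the DG of the rat hippocampus, in a control group and at 7 periods after perforant pathway stimulation, with 3 libraries in each of the 24 groups. The 54 libraries of the control group and of the periods up to 16 days held 1891656 to 4120659 counts (median 2853816). The 18 libraries of the first seizure and the chronic period held 5154825 to 13411245 counts. All deeper libraries belong to the 2 last periods and none to the controls. For these periods, comparisons with control therefore cannot tell a batch of sequencing or preparation from the group. A library detected 485 to 538 miRNAs, and its most abundant miRNA took 9.58% to 31.4% of its counts. Comparisons with control ask how the loaded miRNA pool changed from the hours after stimulation through the silent period to spontaneous seizures. Values are log2 fold changes against control with SE, and levels are means in CPM ± SD, with n = 3 libraries in each group. For the miRNAs given as the largest rises and falls of a period, all 3 libraries lay beyond all 3 controls. A difference between subfields was tested on its own and is given after the periods; a call in 1 subfield and not in another is not a difference between them.

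**Figure D1:**
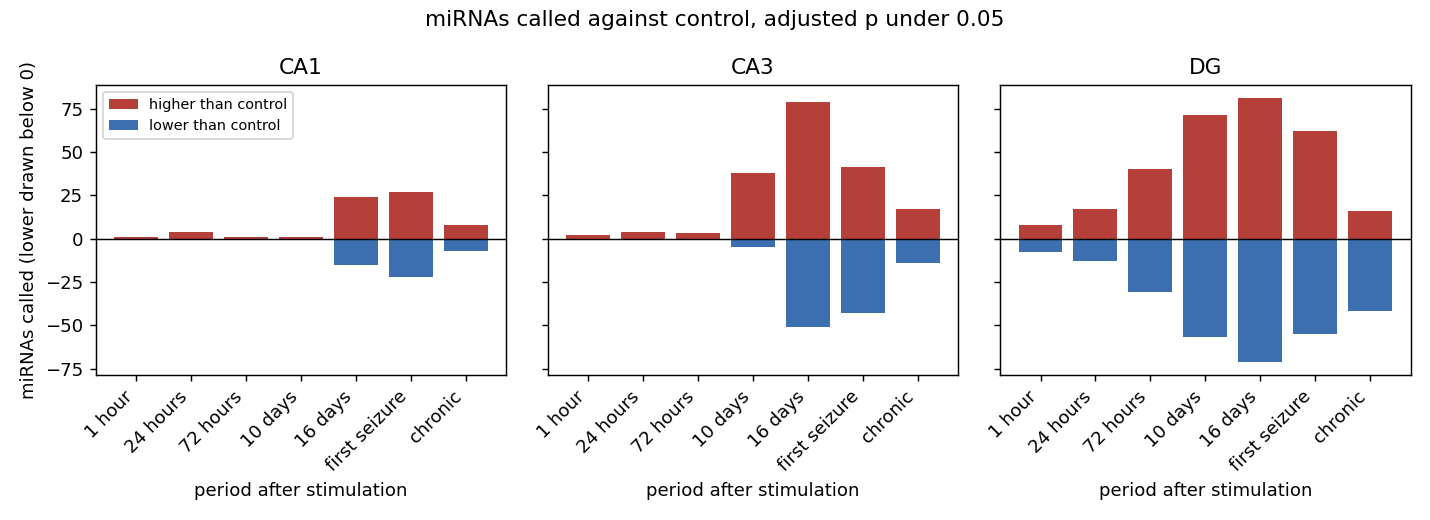
Number of miRNAs called against control at each period, higher and lower, in CA1, CA3 and the DG (edgeR, adjusted p under 0.05). The count was highest at 16 days in CA3 with 130 and in the DG with 152, and at the first seizure in CA1 with 49.

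At 1 hour after stimulation members of the miR-132/miR-212 cluster, which neuronal activity induces through CREB, rose in the DG and CA3. In the DG miR-132-3p went from 2523 ± 362 to 5905 ± 266 CPM, a log2 fold change of 1.23 (SE 0.19, adjusted p = 0.000529), and miR-212-5p rose by 1.48 (SE 0.23). There miR-212-3p rose by 1.18 (SE 0.27). In CA3 miR-212-5p rose from 104 ± 4.34 to 295 ± 63.3 CPM (adjusted p = 0.0237) and miR-132-3p by 1.29 (SE 0.27, adjusted p = 0.0283). In CA1 the change of miR-132-3p was 1.00 (SE 0.28) and did not pass (adjusted p = 0.133). In the DG miR-155-5p, which inflammatory signals induce, rose from 2.33 ± 1.46 to 18.6 ± 6.97 CPM (2.97, SE 0.83, adjusted p = 0.0471), and miR-129-5p rose by 0.65 (SE 0.17). In the same subfield miR-200b-3p, miR-200a-3p and miR-429, a family of epithelial cells, fell by 4.92, 4.87 and 4.82 on the log2 scale. Among the controls library 17 held 57.3 CPM of miR-200a-3p and the others 9.03 and 10.1 CPM. miR-182 of the sensory-cell cluster miR-183/miR-96/miR-182, whose list was too short for a test, fell by 3.21 in the DG (SE 0.83, adjusted p = 0.0315). In CA1 miR-127-3p rose by 3.30 (SE 0.52, adjusted p = 0.00101); its level differed between title numbers in all 3 subfields. It was low in all 3 control libraries in CA1, and in control libraries 17 and 20 in CA3 and the DG.

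At 1 hour edgeR called 1 of 422 miRNAs in CA1 (higher), 2 of 436 in CA3 (both higher) and 16 of 436 in the DG (8 higher, 8 lower). By camera the miR-132/miR-212 list was higher than other miRNAs in CA1 (adjusted p = 0.000159), CA3 (2.88e-09) and the DG (1.25e-09). It had an adjusted p = 0.298 in CA1, 0.152 in CA3 and 0.0428 in the DG with an estimated correlation, so that the DG call held; of the 34, 30 and 29 list calls over all periods in CA1, CA3 and the DG it was the only one to hold. Of its 4 members 0, 2 and 4 were called over all miRNAs, and 2, 4 and 4 adjusted over the list alone. The let-7 list was lower in CA1 (adjusted p = 0.000122; adjusted p = 0.367 with an estimated correlation), where 3 of 9 members were lower adjusted over the list alone. It was also lower in CA3 (adjusted p = 0.000645; adjusted p = 0.572 with an estimated correlation), where 0 were lower. The choroid plexus list, which holds the miR-200 family, was lower in CA3 (adjusted p = 0.000232; adjusted p = 0.572 with an estimated correlation) and in the DG (adjusted p = 0.00216; adjusted p = 0.366 with an estimated correlation). In it 2 of 11 members in CA3 and 4 of 10 in the DG were lower adjusted over the list alone. Leaving out control library 17 gave 3 calls in the DG and 0 in CA3; leaving out control library 20 or the 1 hour library 26 gave 0 in CA3. DESeq2 called 10 in CA1, where the count was 8 when only the 2 groups were fitted and 2 with a choroid plexus marker in the model.

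At 24 hours the inflammation-associated miR-155-5p and miR-21-3p rose in all 3 subfields. miR-155-5p went from 2.67 ± 1.65 to 38.3 ± 9.59 CPM in CA1 (3.83, SE 0.75, adjusted p = 0.0191), and rose by 4.32 (SE 0.81) in CA3 and 4.07 (SE 0.82) in the DG. miR-21-3p, the passenger arm of the inflammation-associated miR-21, rose by 2.58 (SE 0.57) in CA1, from 15.2 ± 4.18 to 90.8 ± 3.54 CPM, by 2.34 (SE 0.54) in CA3 and by 3.40 (SE 0.56) in the DG. In the DG miR-27a-5p rose from 0.818 ± 0.635 to 18.3 ± 0.847 CPM (4.47, SE 0.51, adjusted p = 9.99e-06), miR-147 by 4.95 (SE 1.05), the myeloid miR-223-3p by 3.74 (SE 0.62) and miR-21-5p by 1.67 (SE 0.48). In CA3 miR-27a-5p rose by 3.09 (SE 0.67). miR-3473 rose by 3.51 in CA1 (SE 0.83), 5.01 in CA3 (SE 0.81) and 5.34 in the DG (SE 0.88). Library 11 held 73.8, 299 and 123 CPM, and the other 24 hour libraries 7.55 to 47.7 CPM. miR-132-3p rose by 1.30 in CA1 (SE 0.28) and 1.27 in the DG (SE 0.19). Among falls in the DG were the neuronal miR-124-3p (-0.57, SE 0.15, adjusted p = 0.0192) and miR-29a-3p (-0.63, SE 0.16). The neuron list did not pass by camera in the DG (adjusted p = 0.716), with 1 of 11 members called higher and 1 lower. The miR-200 family fell there too (miR-200a-3p -4.79, miR-429 -4.71, miR-200b-3p -3.75), with uneven controls as at 1 hour.

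At 24 hours edgeR called 4 miRNAs in CA1, 4 in CA3, all higher, and 30 in the DG (17 higher, 13 lower; 17 and 8 on total counts without a TMM factor). With DESeq2 the counts were 13 in CA1 (4 lower) and 15 in CA3 (1 lower), and when only the 2 groups were fitted 18 and 15 (2 lower in each). The inflammation list was higher by camera in CA1 (adjusted p = 0.000266; adjusted p = 0.238 with an estimated correlation), CA3 (adjusted p = 0.0136; adjusted p = 0.596 with an estimated correlation) and the DG (adjusted p = 0.00718; adjusted p = 0.401 with an estimated correlation). Of its 10 members 2, 2 and 5 were called higher, and 7, 4 and 5 were higher and 1, 0 and 1 lower adjusted over the list alone. The microglia and leukocyte list was higher in CA1 (adjusted p = 0.000445; adjusted p = 0.298 with an estimated correlation), CA3 (adjusted p = 0.00252; adjusted p = 0.572 with an estimated correlation) and the DG (adjusted p = 0.00263; adjusted p = 0.366 with an estimated correlation). In it 1 of 5, 1 of 5 and 2 of 6 members were called, and 4, 3 and 4 adjusted over the list alone. The miR-132/miR-212 list was higher by camera in the DG (adjusted p = 3.82e-05, and 0.356 with an estimated correlation). There 3 of 4 members were called, and 4 adjusted over the list alone. It was also higher in CA1 (adjusted p = 0.000244, and 0.298 with an estimated correlation) and CA3 (adjusted p = 0.00252, and 0.572). In these 1 and 0 members were called, and 3 in each adjusted over the list alone. In CA1 the red blood cell list was higher (adjusted p = 0.0203, and 0.445 with an estimated correlation), with 0 of 3 members called and 3 adjusted over the list alone. By camera it did not pass in CA3 (median 1.29, adjusted p = 0.112) or the DG (median 1.57, adjusted p = 0.293). In each of these all 4 members had a log2 fold change above 0, and 0 were called. Leaving out any of the control libraries 17, 20 and 31 gave 0 calls in CA1, and leaving out library 11 gave 1. In CA3 the count was 2 without library 15 or control library 20, 1 without control library 17, 7 without library 16 and 10 without the libraries high in the choroid plexus miRNA miR-204-5p. In the DG it was 18 without library 11, 15 or 16.

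At 72 hours the DG continued with rises of inflammation and leukocyte miRNAs, and some miRNAs of the imprinted miR-379-410 cluster, which neurons express, fell. In the DG miR-147 rose by 4.97 (SE 1.05), miR-155-5p by 3.89 (SE 0.82), miR-3473 by 3.53 (SE 0.88), miR-142-3p by 2.71 (SE 0.70) and miR-21-5p by 2.44 (SE 0.49, adjusted p = 0.00551; 3970 ± 1850 against 730 ± 60.2 CPM). miR-379-5p fell from 21.7 ± 8.25 to 5.74 ± 0.302 CPM (-1.91, SE 0.37, adjusted p = 0.00551), miR-411-3p fell by 1.65 and miR-200a-3p by 3.35 on the log2 scale. In CA3 miR-155-5p rose by 3.90 (SE 0.80, adjusted p = 0.0327), miR-212-5p by 1.29 (SE 0.29) and miR-132-3p by 1.26 (SE 0.27), and let-7b-3p fell (-0.86, SE 0.20). In CA1 the only call of edgeR was miR-127-3p (3.24, SE 0.51), with its level low in all 3 control libraries.

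At 72 hours edgeR called 1 miRNA in CA1 (higher; 26 with DESeq2, 33 when only the 2 groups were fitted), 4 in CA3 (3 higher, 1 lower; 20 with DESeq2) and 71 in the DG (40 higher, 31 lower). The split moved with scaling: 3 and 1 with RLE and 3 and 2 with total counts in CA1, 5 and 0 with RLE and 7 and 0 with total counts in CA3, and 39 and 40 with RLE and 34 and 50 with total counts in the DG. The miR-379-410 list was lower by camera in the DG (adjusted p = 3.82e-05, and 0.366 with an estimated correlation). There 11 of 51 members were called lower, and 16 adjusted over the list alone. It was also lower in CA1 (adjusted p = 0.000244, and 0.644 with an estimated correlation), with 0 of 49 members called and 0 adjusted over the list alone. In CA3 it did not pass (adjusted p = 0.107). The inflammation list was higher by camera in the DG (adjusted p = 0.0214, and 0.468 with an estimated correlation). There 6 of 10 members were called higher and 1 lower, likewise adjusted over the list alone. It was also higher in CA1 (adjusted p = 0.0225, and 0.367 with an estimated correlation) and CA3 (adjusted p = 0.00449, and 0.572). In these 0 and 1 members were called. Adjusted over the list alone, 5 and 4 were higher and 1 and 0 lower. In CA3 the miR-132/miR-212 list was higher (adjusted p = 9.31e-05; adjusted p = 0.398 with an estimated correlation), with 2 of 4 members called and 4 adjusted over the list alone. In CA1 the neuron list was lower (adjusted p = 0.0389, and 0.644 with an estimated correlation) with 0 of 11 members called, and 0 adjusted over the list alone. The microglia list was higher by camera in CA1, CA3 and the DG (adjusted p = 0.00585, 0.00385 and 0.00706), but not with an estimated correlation. In it 0, 1 and 4 members were called. The red blood cell list did not pass by camera (adjusted p = 0.425, 0.0839 and 0.468). Its medians were 2.47, 2.30 and 2.51, with 0 members called in each. In CA3 2 of its members were higher adjusted over the list alone. The DG count was 33 without library 1, 39 without control library 20 and 22 when only the 2 groups were fitted. In CA3 it was 0 without library 3 or control library 17 or 20, 1 without control library 31, 13 when only the 2 groups were fitted and 8 without the libraries high in miR-204-5p. In CA1 it was 12 without the CA1 libraries high in it, 10 without library 3, 4 without library 2 and 2 without control library 20.

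At 10 days miRNAs of leukocytes, of vessels and of the proliferation-associated miR-17-92 cluster rose in the DG and in part in CA3. In the DG miR-143-3p of smooth muscle rose by 1.94 (SE 0.30, adjusted p = 0.000481), miR-126a-3p of endothelium by 0.90 (SE 0.18) and miR-92a-3p by 2.23 (SE 0.46). There also miR-155-5p rose by 3.72 (SE 0.82), miR-130b-3p by 3.62 (SE 0.81) and miR-483-3p by 3.23. miR-124-3p fell from 3816 ± 535 to 2027 ± 450 CPM (-0.91, SE 0.15, adjusted p = 0.000524) and the neuronal miR-128-3p by 0.69 on the log2 scale (SE 0.23). Further falls were of miR-200a-3p (-2.91), miR-200b-3p (-2.66) and miR-409a-5p (-2.34). In CA3 miR-483-5p rose by 3.66 (SE 1.01), miR-130b-3p by 3.57 (SE 0.83), the leukocyte miRNA miR-142-3p by 3.33 (SE 0.74, adjusted p = 0.0159) and miR-10a-5p by 2.43 (SE 0.65). There miR-490-5p (-1.66), miR-376a-3p (-1.13) and miR-379-3p (-1.05) fell. miR-10a-5p also rose in the DG, by 1.91 (SE 0.53). In CA1 the only call of edgeR was miR-127-3p (3.10, SE 0.51), low in all 3 control libraries.

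At 10 days edgeR called 1 miRNA in CA1 (higher; 23 with DESeq2), 43 in CA3 (38 higher, 5 lower; 22 and 11 with total counts) and 128 in the DG (71 higher, 57 lower; 67 and 70 with total counts). By camera the vascular list was higher in the DG (adjusted p = 0.00217; adjusted p = 0.366 with an estimated correlation), with all 5 tested members called, and 5 adjusted over the list alone. The miR-17-92 list was higher in CA1 (adjusted p = 0.000446; adjusted p = 0.367 with an estimated correlation), CA3 (adjusted p = 0.00815; adjusted p = 0.670 with an estimated correlation) and the DG (adjusted p = 0.00718; adjusted p = 0.585 with an estimated correlation). Of its 6 members 0, 5 and 6 were called, and 6, 5 and 6 adjusted over the list alone. By camera this list had already been higher in CA1 at 1 hour (adjusted p = 0.0115). At 24 hours it was higher in CA1, CA3 and the DG (adjusted p = 0.00350, 0.0129 and 0.0147). The same held at 72 hours (adjusted p = 0.000266, 0.00385 and 0.00540), with 4 of its members called in the DG. None of these earlier calls held with an estimated correlation. The neuron list was lower in the DG (adjusted p = 0.0442; adjusted p = 0.401 with an estimated correlation), with 3 of 11 members called and 3 adjusted over the list alone. The miR-127/miR-136 list was lower in CA3 (adjusted p = 0.00214, and 0.670 with an estimated correlation), with 0 of 19 members called and 0 adjusted over the list alone. By camera it was lower in CA3 also at 16 days (adjusted p = 0.00317, 6 members called lower and 1 higher) and the first seizure (0.00283, 4 and 1). In the DG it was lower at 16 days (0.0442, 4 and 1) and higher at 1 hour (0.0487, 1 called higher). None of these calls held with an estimated correlation. By camera the miR-379-410 list was lower in CA1, CA3 and the DG (adjusted p = 0.00283, 7.27e-08 and 2.35e-05), with 0, 3 and 15 members called. The microglia list was higher in each (adjusted p = 0.00341, 0.0113 and 0.00541), with 0, 3 and 5 members called. It had also been higher in CA1 at 1 hour (adjusted p = 0.00341). With an estimated correlation none of these passed. The CA3 count rested on single libraries: it was 152 without library 9, 11 without library 4 and 1 without library 5. It was 0, 2 and 3 without control libraries 17, 20 and 31, 24 with a choroid plexus marker in the model, 21 without the libraries high in miR-204-5p and 0 when only the 2 groups were fitted by edgeR (84 with DESeq2 on all groups; 132 at an unadjusted p under 0.05 in the fit of all groups). The CA1 count was 21 without library 9, and the DG count 78, 69 and 77 without library 4, library 5 and control library 20. The DG count was 24 with the choroid plexus marker in the model and 66 when only the 2 groups were fitted.

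At 16 days the calls of edgeR in CA3 and the DG were more than at the other periods, in the fit of all groups. With a choroid plexus marker in the model the DG had 75 calls, against 76 at the first seizure. The inflammation miRNA miR-146a-5p was among the largest rises in each subfield. It went from 195 ± 136 to 4227 ± 2470 CPM in CA3 (4.44, SE 0.83, adjusted p = 0.00259), and rose by 4.15 in the DG (SE 0.88, adjusted p = 0.00210) and 3.39 in CA1 (SE 0.78, adjusted p = 0.0373). miR-155-5p rose by 2.82 (SE 0.74) in CA1, 4.91 (SE 0.82) in CA3 and 4.39 (SE 0.83) in the DG, and miR-142-3p by 3.90 (SE 0.76) in CA3 and 3.81 (SE 0.72) in the DG. miR-142-5p rose by 2.04 (SE 0.62), 3.03 (SE 0.70) and 2.98 (SE 0.57) in CA1, CA3 and the DG. miR-92a-3p of the miR-17-92 cluster rose by 1.80 (SE 0.50), 2.30 (SE 0.48) and 2.75 (SE 0.47) in CA1, CA3 and the DG. miR-211-5p rose by 2.64 (SE 0.71), 2.66 (SE 0.53) and 2.71 (SE 0.54). Falls were given by miR-136-5p of the Dlk1-Dio3 region (-2.06 in CA3, SE 0.39, adjusted p = 0.00259), miR-138-1-3p (-2.05 in CA3) and the dendritic miR-134-5p (-0.54 in the DG, SE 0.19, adjusted p = 0.0353). The miR-200 family fell in CA1 (miR-429 -4.46, miR-200a-3p -4.37, miR-200b-3p -3.43), where control library 17 held 283, 72.2 and 108 CPM of the 3 and the other controls 3.99 to 27.1 CPM. It also fell in the DG (miR-200a-3p -4.65, miR-429 -3.83, miR-200b-3p -3.33), and miR-429 in CA3 (-2.63). In CA1 miR-127-3p rose by 3.86 (SE 0.53), low in all 3 control libraries.

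At 16 days edgeR called 39 miRNAs in CA1 (24 higher, 15 lower; 13 and 26 with total counts), 130 in CA3 (79 higher, 51 lower) and 152 in the DG (81 higher, 71 lower; 77 and 81 with total counts). The miR-17-92 list was higher by camera in CA1 (adjusted p = 0.000266; adjusted p = 0.367 with an estimated correlation), CA3 (adjusted p = 0.00103; adjusted p = 0.572 with an estimated correlation) and the DG (adjusted p = 0.000362; adjusted p = 0.430 with an estimated correlation), with 4, 5 and 6 of its members called. Adjusted over the list alone, 6 passed in each. The miR-379-410 list was lower in CA1 (adjusted p = 1.51e-07; adjusted p = 0.512 with an estimated correlation), CA3 (adjusted p = 5.19e-08; adjusted p = 0.596 with an estimated correlation) and the DG (adjusted p = 6.52e-07; adjusted p = 0.366 with an estimated correlation). Of its 49, 49 and 51 members 3, 17 and 27 were called lower, and 3, 25 and 32 adjusted over the list alone, with median log2 fold changes of -0.71, -0.78 and -0.67. The microglia list was higher by camera in the DG (adjusted p = 0.00737, and 0.401 with an estimated correlation), with 4 of 6 members called and 5 adjusted over the list alone. It was also higher in CA1 (adjusted p = 0.0486, and 0.545 with an estimated correlation), with 3 of 5 members called. In CA3 it did not pass (adjusted p = 0.0520), with 3 of 5 members called. The oligodendrocyte list was higher in CA1 (adjusted p = 0.0225; adjusted p = 0.570 with an estimated correlation), with 1 of 5 members called and 3 adjusted over the list alone; miR-219a-5p changed by 1.14 (SE 0.42) and did not pass (adjusted p = 0.0852). By camera the miR-181 list passed at no period in any subfield, though fry called it in the DG at 72 hours, 10 days and 16 days (adjusted p = 0.0104, 0.0306 and 0.0295). Its adjusted p by camera was 0.112 in CA1 at 16 days, where miR-181a-5p rose by 1.07 (SE 0.30, adjusted p = 0.0373). The CA1 count was 1 without library 6 or control library 17 or 31, 2 without control library 20, 19 without library 28 and 68 without library 19. It was 2 with a choroid plexus marker in the model, 8 when only the 2 groups were fitted and 72 with DESeq2. In CA3 it was 76, 71 and 79 without library 28, control library 17 and control library 20, and in the DG it was 75 with the choroid plexus marker.

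**Figure D2:**
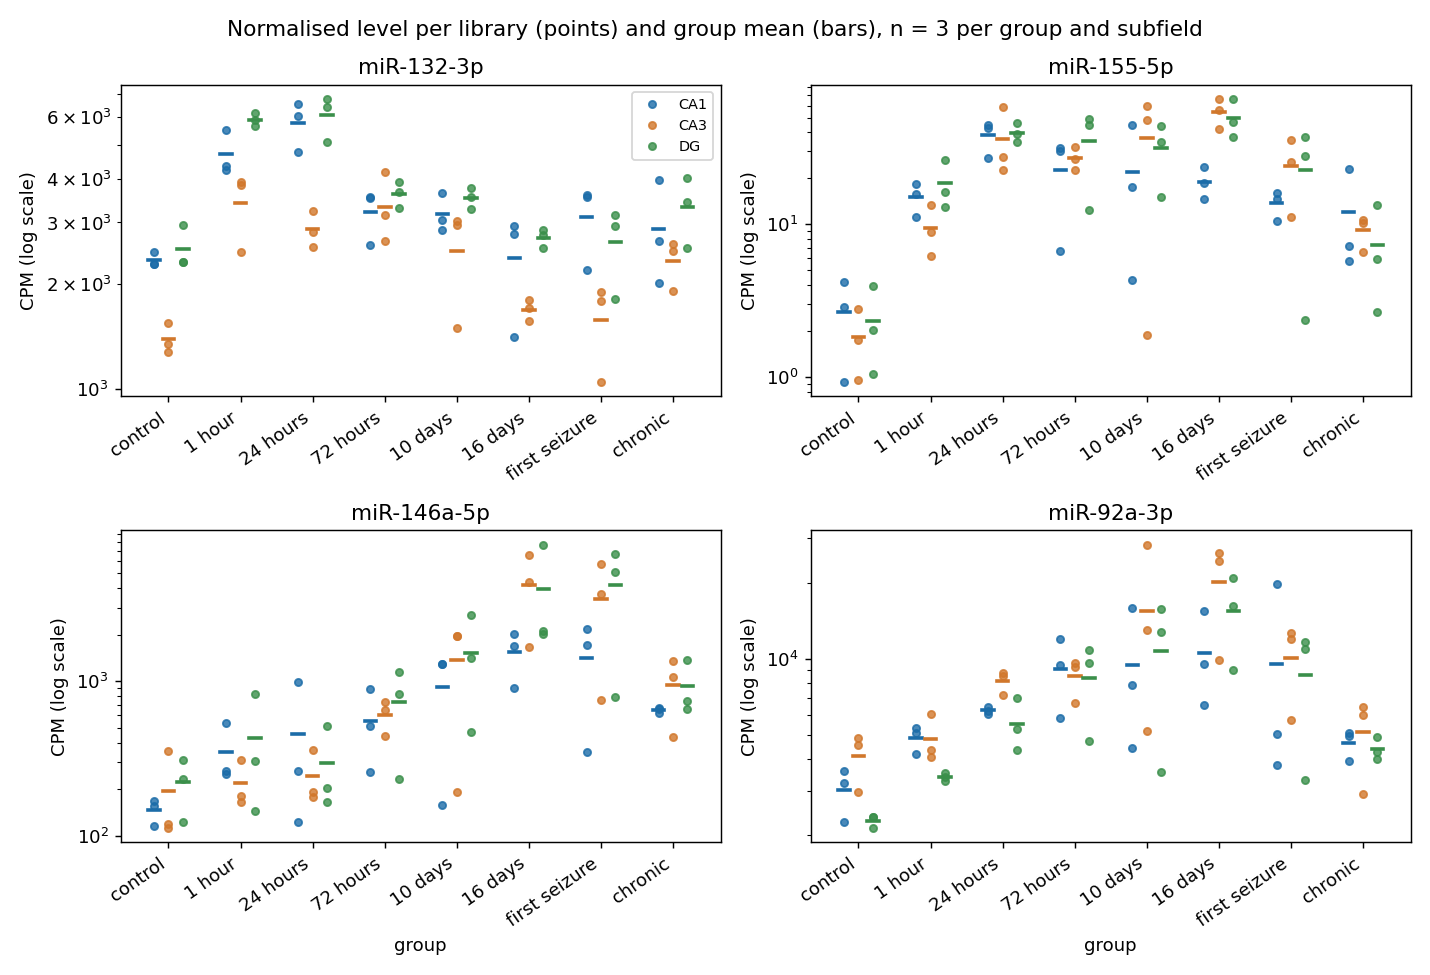
Levels of miR-132-3p, miR-155-5p, miR-146a-5p and miR-92a-3p by group in CA1, CA3 and the DG, in CPM on a log axis, with points for libraries and bars for the means of 3. miR-132-3p was called higher at 1 and 24 hours in the DG, at 1 and 72 hours in CA3 and at 24 hours in CA1. miR-146a-5p was called higher at 10 days, 16 days and the first seizure in CA3 and the DG, and at 16 days and the first seizure in CA1.

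On the day of the first seizure, miR-146a-5p and miR-211-5p were high in all 3 subfields, and miR-376c-3p of the Dlk1-Dio3 region was low. miR-146a-5p rose by 3.26 (SE 0.78, adjusted p = 0.0114) in CA1, 4.13 (SE 0.82, adjusted p = 0.00212) in CA3 and 4.24 (SE 0.88, adjusted p = 0.00222) in the DG, and miR-211-5p by 2.88 (SE 0.70), 3.39 (SE 0.54) and 2.46 (SE 0.53). miR-376c-3p of the miR-379-410 cluster fell by 2.10 (SE 0.48), 2.76 (SE 0.44) and 2.24 (SE 0.28, adjusted p = 1.74e-05) on the log2 scale. miR-153-5p fell in CA1 from 76.1 ± 4.08 to 21.9 ± 7.60 CPM (-1.80, SE 0.28, adjusted p = 0.000535) and by 1.76 in the DG (SE 0.20, adjusted p = 1.13e-05). miR-551b-3p fell by 1.75 in CA1 (SE 0.43), and in CA3 miR-539-3p (-2.09) and miR-154-5p (-2.05) fell. miR-155-5p rose in CA3 (3.73, SE 0.79) and miR-92a-1-5p in the DG (2.80). miR-486 rose by 1.16, 1.10 and 1.04 in CA1, CA3 and the DG (SE 0.32, 0.29 and 0.25). The red blood cell list that holds it did not pass by camera, with medians of 0.91, 0.67 and -0.21. In the DG miR-200a-3p (-4.63), miR-200b-3p (-3.61) and miR-429 (-3.12) fell, and miR-127-3p rose by 4.26 there and by 4.93 in CA1 (SE 0.56, adjusted p = 6.46e-06). It was low in all 3 control libraries in CA1, and in 17 and 20 in the DG.

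At the first seizure edgeR called 49 miRNAs in CA1 (27 higher, 22 lower), 84 in CA3 (41 higher, 43 lower; 48 and 43 with RLE, 43 and 38 with total counts) and 117 in the DG (62 higher, 55 lower). These libraries were sequenced deeper than all controls, and with all libraries thinned to 1 depth the counts were 45, 81 and 113, with 53 higher and 60 lower in the DG. The miR-379-410 list was lower by camera in CA1 (adjusted p = 0.000266; adjusted p = 0.644 with an estimated correlation), CA3 (adjusted p = 3.26e-09; adjusted p = 0.572 with an estimated correlation) and the DG (adjusted p = 0.00216; adjusted p = 0.468 with an estimated correlation). Of its members 5, 17 and 13 were called lower and 1 higher in each, and 5, 22 and 13 lower adjusted over the list alone. The let-7 list was lower in CA1 (adjusted p = 0.00253; adjusted p = 0.512 with an estimated correlation) and CA3 (adjusted p = 0.00252; adjusted p = 0.572 with an estimated correlation). In it 3 and 6 of 9 members were called, and 6 in each adjusted over the list alone. By camera the let-7 list was lower in CA1 and CA3 also at 72 hours (adjusted p = 0.0369 and 0.00271) and in the chronic period (0.00341 and 0.00459). In each of these 0 members were called, and none of these calls held with an estimated correlation. The seizure-associated list was higher by camera in the DG (adjusted p = 0.0134, and 0.366 with an estimated correlation), with 8 of 23 members called and 10 adjusted over the list alone. It was also higher in CA1 (adjusted p = 0.0208, and 0.298 with an estimated correlation) and CA3 (adjusted p = 0.0171, and 0.572). In these 3 and 7 members of the list were called, and as many adjusted over the list alone. By camera this list was also higher in CA1, CA3 and the DG at 1 hour (adjusted p = 0.000225, 0.000645 and 0.00334). The same held at 24 hours (0.00832, 0.0324 and 0.0104), 72 hours (0.0351, 0.000645 and 0.0145) and in the chronic period (0.00832, 0.00214 and 0.0442). It passed in no subfield at 10 or 16 days, so its calls were not particular to the first seizure. None held with an estimated correlation. These calls are not independent evidence where the members of the list were known from these samples. The CA1 count was 14 without library 64, and 74 without library 69. It was 27, 20 and 25 without control libraries 17, 20 and 31, and 1 when only the 2 groups were fitted. In CA3 it was 45, 55, 47 and 54 without library 64, library 69, control library 17 and control library 20, and 129 without the libraries high in the choroid plexus miRNA miR-204-5p. In the DG it was 60 and 76 without library 69 and control library 20, 76 with the choroid plexus marker in the model (35 higher, 41 lower) and 55 when only the 2 groups were fitted.

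In the chronic period miR-328b-3p was higher in all 3 subfields, and the p53 target miR-34a-5p in CA3 and the DG. miR-328b-3p rose from 8.67 ± 3.93 to 40.4 ± 5.27 CPM in CA1 (2.22, SE 0.48, adjusted p = 0.0190), by 2.59 in CA3 (SE 0.49, adjusted p = 0.00945) and by 2.14 in the DG (SE 0.36, adjusted p = 0.000876). miR-34a-5p rose by 2.36 (SE 0.46) in CA3 and 1.56 (SE 0.43) in the DG, and miR-1249 by 2.74 (SE 0.52) in the DG. miR-129-5p rose by 0.67 in the DG (SE 0.17). In CA1 miR-381-3p rose by 2.02 (SE 0.54), while miR-376c-3p (-2.29, SE 0.49), miR-136-5p (-1.69, SE 0.47) and miR-335 (-1.17, SE 0.29) fell. In CA3 miR-379-5p rose by 2.94 (SE 0.71), with 41.5 ± 38.4 against 5.33 ± 2.91 CPM. miR-29a-3p, which is higher in cultured astrocytes, fell by 0.67 on the log2 scale in the DG (SE 0.16). The miR-200 family fell in CA3 (miR-200a-3p -3.92, miR-429 -3.56, miR-200b-3p -3.26) and the DG (miR-200a-3p -4.50, miR-200b-3p -4.03, miR-429 -3.33), with library 17 the highest control. miR-127-3p rose by 4.63 in CA1 (SE 0.55, adjusted p = 1.43e-05), 2.61 in CA3 (SE 0.57) and 3.65 in the DG (SE 0.78). It was low in all 3 control libraries in CA1, and in 17 and 20 in CA3 and the DG.

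In the chronic period edgeR called 15 miRNAs in CA1 (8 higher, 7 lower; 14 and 3 with total counts), 31 in CA3 (17 higher, 14 lower; 30 and 11 with total counts) and 58 in the DG (16 higher, 42 lower; 25 and 37 with RLE, 38 and 32 with total counts). The miR-23/26/29 list was lower by camera in the DG (adjusted p = 0.0274; adjusted p = 0.454 with an estimated correlation), with 3 of 7 members called and 4 adjusted over the list alone. The neuron list was higher in CA3 (adjusted p = 0.0207; adjusted p = 0.670 with an estimated correlation) with 0 of 11 members called and 0 adjusted over the list alone. The miR-379-410 list was lower by camera in the DG (adjusted p = 0.0145, and 0.609 with an estimated correlation). There 9 of 51 members were called lower and 1 higher, and 12 lower and 3 higher adjusted over the list alone. It was also lower in CA1 (adjusted p = 0.00319, and 0.743 with an estimated correlation), with 1 of 49 members called lower and 1 higher. In CA3 it did not pass (adjusted p = 0.0520). The CA1 count was 8, 5 and 27 without libraries 37, 43 and 75, and 2, 2 and 1 without control libraries 17, 20 and 31. It was 9 with the choroid plexus marker in the model, 6 without the libraries high in miR-204-5p, 24 when only the 2 groups were fitted (11 higher, 13 lower) and 41 with DESeq2 (20 higher, 21 lower). In CA3 it was 15 without control library 17, 9 without control library 20, 5 when only the 2 groups were fitted and 57 with DESeq2. In the DG it was 36 without library 43 and 26 with the choroid plexus marker, and the balance was 31 and 27 when only the 2 groups were fitted.

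**Figure D3:**
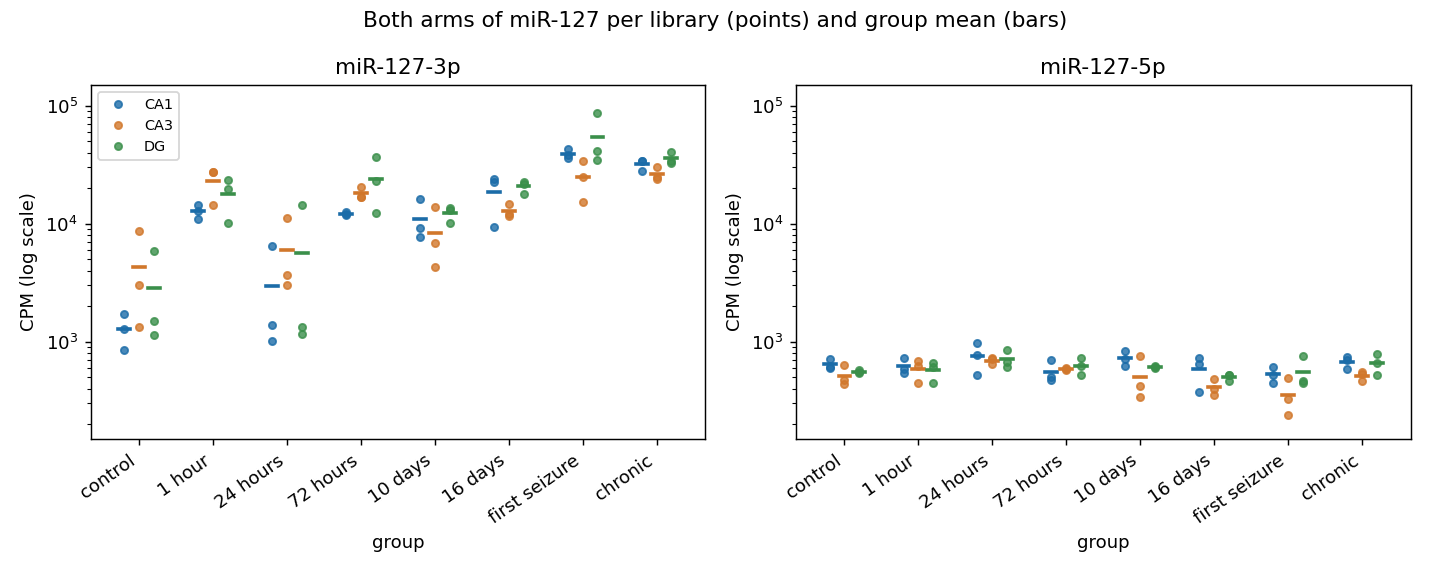
Levels of miR-127-3p and miR-127-5p by group in CA1, CA3 and the DG, in CPM on a log axis, with 1 point per library. Over title numbers the mean level ranged over 5.45 on the log2 scale for miR-127-3p and 1.15 for miR-127-5p.

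The chronic period was compared directly with the first seizure, a comparison that stays within the deeper libraries and asks what differed once seizures were established. edgeR called 0 of 422 miRNAs in CA1 (44 at an unadjusted p under 0.05; 0 with DESeq2), 0 of 436 in CA3 (108 at an unadjusted p under 0.05; 14 with DESeq2) and 1 of 436 in the DG (59 at an unadjusted p under 0.05; 2 with DESeq2). The DG call was the endothelial miR-126a-5p, lower in the chronic period (-0.86, SE 0.18, adjusted p = 0.0340), named after its values were seen. The DG count was 0 without library 64, 74, 37, 43 or 75, and also with RLE, with total counts, without the filter and with the choroid plexus marker in the model.

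The test of whether any period differed from control gave 46 miRNAs in CA1 (131 with DESeq2), 166 in CA3 and 236 in the DG. miR-132-3p passed it in the DG with an adjusted p = 6.61e-05 and in CA3 with an adjusted p = 0.00463. Leaving out single libraries moved the CA1 count to 28 without 24 hour library 16, 26 without 10 day library 4, 77 without first seizure library 69, 25 without chronic library 43, and 23, 23 and 24 without control libraries 17, 20 and 31.

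Between the subfields of controls, 3 miRNAs of oligodendrocytes were lower in the DG than in CA3; no list was tested here. miR-219a-5p was at 195 ± 26.7 CPM in the DG and 719 ± 293 CPM in CA3 (-1.88, SE 0.43, adjusted p = 0.0254), miR-338-3p differed by -1.49 (SE 0.36, adjusted p = 0.0265) and miR-219a-2-3p by -1.71 (SE 0.44, adjusted p = 0.0476). These were the 3 calls of edgeR among 451 miRNAs (5 with total counts, 1 of them higher), and without control library 17, 20 or 31 the counts were 0, 1 and 0. miR-592 was lower in CA3 (29.9 ± 16.2 CPM) than in CA1 (104 ± 23.7 CPM), by -1.79 (SE 0.40, adjusted p = 0.0172), the only call of edgeR between these (2 with DESeq2, 12 when only the 2 groups were fitted); without control library 20 or 31 the count was 0. Between the DG and CA1 edgeR called 0, with 40 at an unadjusted p under 0.05 5 with DESeq2, 1 with total counts and 2 when only the 2 groups were fitted. With the title number as a replicate block edgeR called 5 between these (miR-34a-5p, miR-490-5p, miR-490-3p and miR-592 lower and miR-99b-5p higher in the DG, named after their values were seen) and 6, all lower, between the DG and CA3.

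The subfields' responses were compared by interaction terms, which ask whether a period changed a miRNA to a different degree in CA1, CA3 and the DG. edgeR called 0 of 451 miRNAs over all periods together (21 at an unadjusted p under 0.05; 0 with DESeq2) and 0 at 1 hour, 24 hours, 10 days, 16 days, the first seizure and the chronic period (8, 3, 6, 18, 17 and 27 at an unadjusted p under 0.05; 0 with DESeq2 in each). At 72 hours 1 miRNA was called by edgeR and 1 by DESeq2: miR-203a-3p, a miRNA of squamous epithelium (adjusted p = 0.0400), with log2 fold changes of 0.52 in CA1 (SE 0.80), -0.52 in CA3 (SE 0.80) and 4.85 in the DG (SE 0.93). DG library 1 held 7900 CPM of it and the other 72 hour libraries 97.2 and 70.6 CPM, and without the libraries numbered 1, or without those of control number 17, 20 or 31, the count was 0. With the title number as a replicate block it was also 0, and the other counts of this test stayed 0. The 10 miRNAs with the smallest p over all periods, miR-145-3p, miR-143-3p, miR-203a-3p, miR-199a-5p, miR-450a-5p, miR-450b-5p, miR-219a-5p, miR-379-5p, miR-199a-3p and miR-338-3p, had an adjusted p of 0.551 to 0.757. In simulated data this test recovered 65.2% of 4-fold and 14.9% of 2-fold differences at 16 days among 451 miRNAs. The larger number of calls in the DG is therefore not shown to be a difference in response. Without chronic library number 75 the chronic count was 19, without 16 day number 6 the 16 day count was 1, and without 10 day number 4 the count over all periods was 2.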

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

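The tests weighed here on miR-127-3p, on the late periods and on the DG at 16 days were chosen after the results were seen; the test of a difference between subfields was planned.

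miR-203a-3p at 72 hours differed between subfields in its response (interaction adjusted p = 0.0400, edgeR), with log2 fold changes of 4.85 in the DG, 0.52 in CA1 and -0.52 in CA3. The difference came with 1 DG library: number 1 held 7900 CPM, against 97.2 and 70.6 CPM in the other 72 hour libraries and 72.4, 69.5 and 137 CPM in the DG controls. Without number 1 the count of calls was 0, and it was also 0 with the title number as a replicate block. Of 10 splits of the title numbers, 7 gave as many calls as the real one. Its source was not tested, and no biological explanation was tested.

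miR-127-3p differed between title numbers, for the most part alike in the 3 subfields. Control 31 was an exception, with 1788 CPM in CA1, 8817 CPM in CA3 and 5716 CPM in the DG. Over title numbers the mean level of miR-127-3p ranged over 5.45 on the log2 scale. Each number belongs to 1 period, so this range includes differences between periods. Low values of miR-127-3p were found in controls 17 and 20, in control 31 in CA1, and in the 24 hour libraries 15 and 16. Transcription of its cluster as a source is argued against by the other 17 members with at least 10 CPM, none of which ranged over more than 2.36, with miR-127-5p from the same hairpin at 1.15. Of the variance within periods 80.0% lay between title numbers, so that a sequence variant in single animals and the handling of single numbers both stay open and cannot be told apart, since the labels give neither genotype nor batch. The rise of miR-127-3p against control could therefore come in part from which numbers are the controls.

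The calls at the first seizure and in the chronic period come from libraries deeper than all controls. Depth alone is argued against: thinned to 1 depth, the counts at the first seizure were 45, 81 and 113 in CA1, CA3 and the DG, against 49, 84 and 117, though the balance in the DG went from 62 higher and 55 lower to 53 and 60. A batch as the whole cause of these calls as 1 pooled set, most of them from the first seizure, is also argued against by the shallower libraries. There the signed mean of the 56, 96 and 128 miRNAs called at either period was higher at 10 and 16 days than at 1 and 24 hours. The difference was 0.294, 0.628 and 0.464 log2 (exact two-sided permutation p = 0.0390, 0.0152 and 0.0152 over 924 regroupings of 12 libraries). In each subfield 5 of 6 later libraries lay above all earlier ones. How many of these miRNAs moved that way was not counted, so a batch may be the whole cause for some of them. Of the 56, 96 and 128 miRNAs 49, 84 and 117 were called at the first seizure, and these took their sign from there. The calls of the chronic period were not tested on their own, so for them a batch as the whole cause stays open. A batch as part of the cause stays open, because the deeper libraries include no control. Progress of the disease, which the design names, stays open as well.

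In the DG at 16 days the microglia and miR-17-92 lists were higher and the miR-379-410 list lower, a pattern that a shift in cell composition could give. A lower share of neurons as the whole source would raise the markers of every other cell type alike. The microglia markers averaged 2.58 and the oligodendrocyte markers 0.27, a difference of 2.31, which argues against it for these 2 lists. The vascular markers lay between them, with a mean of 0.66 and a median of 0.92 (4 of 5 higher adjusted over the list alone). The exact permutation p for microglia against oligodendrocyte markers was 0.0195. It does not decide the question, since the microglia list was chosen because it rose and miRNAs are not independent replicates. A lower share as part of the source stays open, since 4 of 11 neuron markers were called lower and 0 higher (median -0.42; adjusted p = 0.183 by camera and 0.0185 by fry). Choroid plexus tissue as the whole source is argued against by its marker miR-204-5p, which changed by 0.30 (SE 0.41, adjusted p = 0.591), against a median of 2.85 for the miR-17-92 list. As part of the source it stays open: the score of 4 choroid plexus markers was 0.51, 0.04 and 0.28 in the 16 day libraries, above all controls (-0.71, -0.48 and -0.21). With that score in the model the count of calls went from 152 to 75. Since the score goes with the group, calls can be lost whatever their source, so this fall does not decide the question. A change in microglia or leukocytes themselves, in number or in content, stays open as a hypothesis; 3 microglia markers stand in other lists, and the sorting of cells that would separate these was not part of the design.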

How the results depend on the processing

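The choroid plexus covariate, the fit without libraries high in miR-204-5p, thinning and the comparison of the chronic period with the first seizure were chosen after the data were seen; the other alternatives were planned. Among the named miRNAs whose direction was checked, none that was called changed it under any alternative run. The direction of the other called miRNAs was not checked. The balance of higher and lower calls turned with total counts in CA1 at 16 days (24 and 15 to 13 and 26), in CA3 at the first seizure (41 and 43 to 43 and 38; 48 and 43 with RLE), and in the DG at 72 hours (40 and 31 to 34 and 50; 39 and 40 with RLE), 10 days (71 and 57 to 67 and 70), 16 days (81 and 71 to 77 and 81) and the chronic period (16 and 42 to 38 and 32). With DESeq2 it turned in CA1 at 1 hour (1 and 0 to 4 and 6) and in the chronic period (8 and 7 to 20 and 21), in CA3 at the first seizure (62 and 55) and in the DG at 72 hours (48 and 51). With only the 2 groups it turned in CA1 in the chronic period (11 and 13), in CA3 at the first seizure (54 and 52) and in the DG in the chronic period (31 and 27), and without the filter in CA3 at the first seizure (41 and 40) and in the DG at 16 days (78 and 81). With the covariate it turned in CA3 in the chronic period (17 and 14 to 13 and 14) and in the DG at the first seizure (62 and 55 to 35 and 41), which also turned when thinned (53 and 60). Without the libraries high in miR-204-5p it turned in CA3 at the first seizure (73 and 56) and in the chronic period (19 and 20). Leaving out control 17 turned it in the DG at 24 hours (17 and 13 to 13 and 16), 72 hours (30 and 36), 10 days (58 and 59), 16 days (67 and 71) and the first seizure (39 and 50). It also turned in CA1 at the first seizure without control 20 or 31 (27 and 22 to 8 and 12 and to 11 and 14) and at 1 hour (1 and 3 in both), in CA3 at 1 hour without library 36 (2 and 0 to 1 and 3) and at the first seizure without 74 (46 and 42), in the DG at 72 hours without library 1 (15 and 18) and at the first seizure without library 64 (38 and 40) or control 31 (46 and 48), and for the DG against CA3 in controls without control 20 (0 and 3 to 1 and 0). Of the results on named miRNAs, 481 kept their side of the threshold with DESeq2 (53 passed it newly, 1 lost it), 529 with RLE (2 and 6), 501 with total counts (11 and 25), 524 without the filter (0 and 13), 285 with only the 2 groups (17 and 42), 464 with the covariate (4 and 55), 101 thinned (0 and 2) and 6016 over the fits that leave out 1 library (102 and 566). Without the libraries high in miR-204-5p, 26 passed it newly and 24 lost it, all in CA1 and CA3, since no DG library was left out. The cause was not tested for any moved count below, except that fewer samples enter where libraries or groups are left out.

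With DESeq2 the counts were 10, 13, 26, 23, 72 and 41 in CA1 at 1 hour, 24 hours, 72 hours, 10 days, 16 days and the chronic period, and 131 for any period; 15, 20, 84 and 57 in CA3 at 24 hours, 72 hours, 10 days and the chronic period; 14 in CA3 and 2 in the DG for chronic against first seizure; and 2 and 5 for CA3 and the DG against CA1 in controls. With only the 2 groups they were 8, 18, 33, 8, 1 and 24 in CA1 (1 hour, 24 hours, 72 hours, 16 days, first seizure, chronic), 15, 13, 0 and 5 in CA3 (24 hours, 72 hours, 10 days, chronic), 22, 66 and 55 in the DG (72 hours, 10 days, first seizure), and 12 and 2 for CA3 and the DG against CA1 in controls. The 0 in CA3 at 10 days is of edgeR, where DESeq2 on all groups called 84 and 132 had an unadjusted p under 0.05 in the fit of all groups.

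With RLE the count was 4 in CA1 at 72 hours and 0 in the DG for chronic against first seizure, where no filter, total counts and the covariate also gave 0 (59 at an unadjusted p under 0.05 as reported; 2 with DESeq2). With total counts it was 5 in CA1 and 7 in CA3 at 72 hours, 1 for the DG against CA1 and 5 for the DG against CA3 in controls. Total counts moved the median of all miRNAs by -0.14, -0.21 and -0.23 log2 in CA1 at 72 hours, 10 days and 16 days, 0.11, -0.15, -0.13 and 0.18 in CA3 at 72 hours, 10 days, 16 days and the chronic period, and 0.13 in the DG in the chronic period.

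With the choroid plexus covariate the counts were 2, 2 and 9 in CA1 at 1 hour, 16 days and the chronic period, 24 in CA3 at 10 days, and 24, 75, 76 and 26 in the DG at 10 days, 16 days, the first seizure and the chronic period. Without the libraries high in miR-204-5p they were 12 and 6 in CA1 at 72 hours and the chronic period, and 10, 8, 21 and 129 in CA3 at 24 hours, 72 hours, 10 days and the first seizure.

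Camera called 34, 30 and 29 lists in CA1, CA3 and the DG; with an estimated correlation 0, 0 and 1 were called, and by fry 10, 11 and 38. Every called list had its median, mean and test on 1 side, and kept the sign of its median with RLE and total counts. Some lists that were not called changed the sign of their median with scaling, such as the choroid plexus list in CA1 at 16 days (0.17, and -0.08 with total counts). In some of them the median, mean and test differed in sign, such as the choroid plexus list in CA1 at 1 hour (median 0.28, mean -0.85, tested lower), the red blood cell list in the DG in the chronic period (median -0.69, tested higher) and the miR-181 list in CA1 at the first seizure (median 0.14, tested lower).

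Over all groups the title numbers do not pair the libraries by the rule set. Correlations of deviations between subfields were over 0.1 in 17, 21 and 21 of 24 pairs (CA3 and CA1, DG and CA1, DG and CA3). The lowest values were -0.387, 0.0156 and -0.179, all in the chronic period, and 19, 21 and 21 of 24 libraries correlated best with their own number. With the replicate number as a block the counts were 5 for the DG against CA1, 6 for the DG against CA3 and 0 for the subfield difference at 72 hours (edgeR; 9 at an unadjusted p under 0.05 and 1 with DESeq2 without the block), and the other counts stayed within 1.5 times.

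Leaving out 1 library at a time gave, for 1 hour, 24 hours, 72 hours, 10 days, 16 days, first seizure, chronic and any period, 1 to 4, 0 to 5, 1 to 10, 1 to 21, 1 to 68, 14 to 74, 1 to 27 and 23 to 77 calls in CA1. In CA3 it gave 0 to 4, 1 to 7, 0 to 3, 0 to 152, 71 to 122, 45 to 88, 9 to 29 and 120 to 237, and in the DG 3 to 13, 18 to 29, 33 to 68, 69 to 138, 113 to 138, 60 to 129, 36 to 61 and 203 to 250. The highest came in CA1 without control 20 or 31 (4), without library 3 (10), 9 (21), 19 (68), 69 (74 and 77) and 75 (27), and in CA3 without library 9 (152). The lowest came without control 17, 20 or 31 (0 in CA1 at 24 hours, 1 without 17 or 31 at 16 days), without library 64 (14 in CA1, 45 in CA3), control 17 (0 in CA3 at 10 days, 71 at 16 days, 3 in the DG at 1 hour), control 20 (9 in CA3, chronic), and libraries 1 (33), 5 (69), 69 (60) and 43 (36) in the DG. In CA3 the 0 at 1 hour came without library 26, control 17 or 20, and at 72 hours without library 3, control 17 or 20. Lists ranged from 29 to 37, 27 to 38 and 27 to 33. The subfield difference ranged from 0 to 1 at 72 hours and 16 days, 0 to 19 in the chronic period (19 without 75) and 0 to 2 over any period (2 without 4); CA3 against CA1 and the DG against CA3 in controls from 0 to 1, and chronic against first seizure 0 to 1, 0 to 2 (2 without 64) and 0 to 1. The counts of 0 are of edgeR; the unadjusted counts under p 0.05 in the fits of all libraries were 56 in CA1 at 24 hours, 21, 78 and 132 in CA3 at 1 hour, 72 hours and 10 days.

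Depth limits the rarer miRNAs: 3 counts were worth up to 1.59 CPM in the shallower libraries, so that for miR-147 (0.332 CPM) and miR-27a-5p (0.818 CPM) in DG controls the fold change depends on the prior count.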

Other observations

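The counts over other splits of the libraries were obtained after the calls had been seen.

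Members of the miR-379-410 cluster went opposite ways late after stimulation. miR-381-3p rose at the first seizure by 1.87 (SE 0.53) in CA1, 1.98 (SE 0.48) in CA3 and 1.27 (SE 0.28) in the DG, where miR-376c-3p of the same cluster fell by 2.10, 2.76 and 2.24 on the log2 scale. let-7 members also parted in the DG at 72 hours: let-7i-5p rose by 0.62 (SE 0.17, adjusted p = 0.0211) and let-7b-5p fell by 0.97 on the log2 scale (SE 0.24, adjusted p = 0.0117). The handling of reads that match several let-7 members is not known, so these values are uncertain to that extent. In the DG miR-183-5p fell by 3.36 at 24 hours, 2.91 at 16 days and 2.68 at the first seizure on the log2 scale.

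Of the libraries, 8 were high in the choroid plexus miRNA miR-204-5p against the median of their subfield (200 CPM in CA1, 393 CPM in CA3): library 24 at 1 hour (876 CPM), 3 at 72 hours (2456 CPM) and 74 at the first seizure (673 CPM) in CA1, and library 1 at 72 hours (4031 CPM), 5 at 10 days (6388 CPM), 19 at 16 days (3486 CPM), 74 at the first seizure (1691 CPM) and 43 in the chronic period (1856 CPM) in CA3.

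Other splits of the same libraries were counted for each comparison. For the test of any period, 1 of 100 splits, the real one, gave as many calls in each subfield. The counts were 46 against 21 at most in CA1, 166 against 64 in CA3 and 236 against 15 in the DG. Groups made at random thus seldom gave as many calls. The random splits did not keep the deeper libraries together, so they do not bear on a batch. For the subfield difference over all periods the real count was 0 and the highest other 9, and 100 of 100 splits gave as many. The other comparisons have 10 splits of 3 against 3, so the share is never under 0.1. In CA1 the real counts and the highest of the other splits were 1 and 0 at 1 hour, 4 and 0 at 24 hours, 1 and 0 at 72 hours, 1 and 0 at 10 days, 39 and 0 at 16 days, 49 and 1 at the first seizure and 15 and 0 in the chronic period. In CA3 they were 2 and 0, 4 and 0, 4 and 0, 43 and 53 (3 of 10 splits gave as many), 130 and 2, 84 and 1, and 31 and 0. In the DG they were 16 and 0, 30 and 0, 71 and 10, 128 and 2, 152 and 0, 117 and 6, and 58 and 0. For chronic against first seizure they were 0 and 28 in CA1 (10 of 10), which points to a structure of those 6 libraries whose nature was not tested, 0 and 0 in CA3 (10 of 10) and 1 and 1 in the DG (2 of 10). In controls they were 1 and 0 for CA3 against CA1, 0 and 0 for the DG against CA1 (10 of 10) and 3 and 3 for the DG against CA3 (2 of 10). Among the 4 splits of the control libraries that part all 3 pairs of title numbers, the highest other count was 0 in each of these comparisons; the 6 splits that part fewer pairs gave up to 3 for the DG against CA3. For the subfield difference by period they were 0 and 0 (10 of 10), except 1 and 3 at 72 hours (7 of 10) and 0 and 3 in the chronic period (10 of 10). The counts of 0 are of edgeR, with the unadjusted and DESeq2 counts given beside each comparison.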
